A study of Rattus norvegicus with 18 samples.

How the data were processed

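Gene expression was measured in 18 samples of rat primary hepatocytes, each hybridised alone to 1 Agilent array with the green dye Cy3. Per the labels' protocols, cryopreserved hepatocytes of male Sprague Dawley rats were precultured for 24 h and then exposed to DMSO or to 1 of 4 compounds at 300 µM for 24 h, and 100 ng of total RNA was labelled with a low-input kit for one-colour arrays. The samples form 6 groups of 3, and the design text calls these independent experiments. The labels do not say whether the experiments used cells of different animals, so p-values measure the spread between these cultures.

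The scanner files hold one array each. Per the file headers, spot intensity was read with Agilent Feature Extraction 10.7.1.1, and the processed intensity is the Cy3 signal after background subtraction and detrending within the array. Each file lists 62976 spots, of which 58717 are probe spots. Between 61.0% and 64.3% of spots lay well above background on an array, no probe spot was saturated, and the 75th percentile of the processed intensity ranged from 421 to 640. The spike-in ratio given in the text is the signal of a dim spike-in control over that of a bright one, in percent. For arrays, their number limits the precision. The deposited tables of the authors hold signal on a linear scale in 2 sets, because the design text names different chip lots. Their scaling is not given in the sources used here. It was checked on probes with a deposited value over 1 (11346 to 11412 per array). There, each column was a constant times the geometric mean of a probe's unflagged spots over the array's 75th percentile (100% within 1%). Dimmer probes were not compared. The column medians lay between 0.045 and 0.075, and there was no centring of genes. These tables were used as an alternative.

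The scanner files carry no column of gene names. A probe was named when the accession in its file, without version, was found in the reference gene table (assembly GRCr8), which named 21109 of 45598 probes and 16581 genes. The other 24489 probes kept their accession and are counted but not named. No probe was matched to Cyp2b1. The file headers name build rn4, and no coordinates are reported.

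The log2 of the processed intensity was averaged over the unflagged spots of a probe, and the 75th percentile of the array was subtracted. Probes with every spot flagged on at least 1 array were left out (435 probes, leaving 45163). A probe was kept when it lay well above background on all 3 arrays of at least 1 group (25306 probes), and a gene was represented by its brightest kept probe, giving 21574 genes, of which 10790 have a plain symbol. Group means of all 18 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called changed at an adjusted p below 0.05. By chance alone a share of 0.05 of the genes would lie at an unadjusted p under 0.05. The errors of fold changes are standard errors of that fit, intervals are at 95%, and the adjusted p-values in the text are limma's with n = 3 per group. DDMB, CDMB and CDEB were set against VC_1 and DDEB against VC_2, as the design text assigns them. Where DDEB is compared with another compound, the tested value is the difference of the effects, each over its own control.

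Of a gene that lay well above background on no array of a group, the fold is a lower bound ("at least N-fold"). It sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own value and the lowest signal among probes well above background. No fold is given where the bound is under 1 or both groups are dim.

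Groups of genes were tested with limma's camera at its preset correlation of 0.01, for 19 lists and 4 compounds (76 tests, adjusted together). Of 7 lists of markers of other cell types, those with at least 5 measured genes were tested as a separate family (12 tests). Member counts are given over all genes and adjusted over the list alone. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The groups, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each compound against its control, the 10 largest rises and 10 largest falls among changed genes with a plain symbol whose 3 treated arrays all lie on one side of all 3 control arrays, and up to 4 members of each list with the largest absolute change. Between compounds it names the 5 largest each way. A fixed set, namely Cyp2b1, Cyp3a1 (now Cyp3a23-3a1), Cyp1a1, Cyp1a2, Cyp4a1, Nqo1, Hmox1, Gclc, Cdkn1a, Mdm2, Atf3, Ddit3, Cyp7a1, Alb and 2 genes that are not reported here, was to be given for every compound. Further members of lists are named in the text by their adjusted p, which was done after their values were seen.

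Slides were read from the array files. Slide 1 held VC_1 and DDMB, slide 2 held VC_2 and DDEB replicates 1 and 2, slide 3 held DDEB replicate 3, and slide 4 held CDMB and CDEB. Only DDEB lay on more than 1 slide. The correlation of arrays on a slide used for the random block (0.446) thus rests on DDEB replicate 3 against replicates 1 and 2. At this value comparisons across slides lose precision by construction, so their counts under that block do not test the slide. Whether replicate numbers pair the samples was checked by correlating the arrays' deviations from their group means. The same numbers of VC_1 and VC_2 correlated at 0.63, 0.468 and 0.808 across genes, so VC_2 against VC_1 was also fitted with the number as a block. This pairing comes from the data and no label states it. The main fit has no pairing and takes VC_1 and VC_2 as independent, also in the differences between DDEB and another compound. Since the controls deviate together, the intervals of those differences may be too wide. No other compared groups met the criterion of 0.1 for every pair.

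The alternatives were other normalizations (quantile, normexp with an offset of 50, a 75th percentile over detected probes, the deposited tables), other filters and probe rules, fits of fewer arrays, the replicate number or the slide as a block, the other or both controls, an intensity trend with a robust prior, stricter thresholds and each replicate left out. The normexp correction was planned on mean spot signals, which these files do not carry, so the median spot and median background signals took their place. The fit was tested on simulated data with 50 genes changed per size, the same spread in every group and noise that is independent between genes. The shares by comparison thus differ only by the draw and do not rank the compounds. Deviations that real arrays share across genes were not simulated. For DDMB against VC_1, 50% of genes changed by 0.5 and 66% of those changed by 1 on the log2 scale were called. For DDEB against VC_2 these shares were 44% and 74%. For CDMB they were 36% and 78%, and for CDEB 36% and 72%, each among 21574 genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.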

Results

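The study exposed rat primary hepatocytes, the main metabolic cells of the liver kept in short-term culture, to compounds that its title calls p-dialkoxy chlorobenzenes and asks about their modes of action. The labels give the compounds only as the codes DDMB, DDEB, CDMB and CDEB. Each was applied at 300 µM for 24 h to 3 cultures, and 3 cultures with DMSO served as control on each of 2 chip lots (VC_1 for DDMB, CDMB and CDEB, and VC_2 for DDEB). After scaling, 21574 genes were compared across 18 arrays. The median SD between replicates was lowest for CDEB (0.0743 on the log2 scale) and highest for DDEB (0.188), with 0.0949 for CDMB, 0.136 for DDMB, 0.148 for VC_1 and 0.141 for VC_2.

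The first question was what DDMB changed against DMSO on the same slide. The cytochrome P450 gene Cyp4b1 showed the largest rise, 4.86-fold, from -4.15 ± 0.32 in VC_1 to -1.87 ± 0.82 with DDMB (log2 signal relative to the 75th percentile, mean ± SD, n = 3; adjusted p = 0.00794). Pck1, which encodes the cytosolic enzyme that commits carbon to glucose synthesis, rose by 1.16 ± 0.20 (log2 ± SE), Abcg5, a subunit of the sterol exporter, by 1.02 ± 0.16, Colq, the collagen tail of acetylcholinesterase, by 1.07 ± 0.20, and the small heat shock protein gene Hspb1 by 0.78 ± 0.11. The neurofilament genes Nefl and Nefm had log2 changes of -1.88 ± 0.38 and -1.75 ± 0.24, with Nefm above background on 2 of 3 DDMB arrays. The somatostatin receptor gene Sstr3 (-1.36 ± 0.12), the male-specific rat P450 gene Cyp2c11 (-1.14 ± 0.13) and the aldehyde dehydrogenase gene Aldh3a1 (-0.94 ± 0.11, adjusted p = 0.00123) fell as well. Unc5d (1.23), Cimip2a (1.00), Cpne9 (0.93), Pcp4l1 (0.86) and Procr (0.76) completed the 10 largest rises. Spon2 (-1.25), Ogn (-1.20), Pla1a (-0.96), Npw (-0.89) and Car11, which was at least 1.54-fold lower, completed the falls.

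Genes of glucose synthesis and amino acid breakdown contributed 5 of their 33 measured members to the DDMB response over all genes and 5 rises and 1 fall adjusted over the list alone. Besides Pck1 these were Tat (0.68), the first enzyme of tyrosine breakdown, Ass1 (0.65) of the urea cycle, the liver glutaminase gene Gls2 (0.39) and Hpd (0.39). The list rose as a whole (median 0.11, adjusted p = 0.00544), with adjusted p = 0.930 with an estimated correlation, and without VC_1 replicate 3 the call was lost (median -0.05, adjusted p = 0.643). Its median was 0.0432 without DDMB replicate 1, 0.254 without DDMB replicate 2 and 0.173 without VC_1 replicate 1. Targets of PPARalpha, the nuclear receptor that governs fatty acid oxidation, shifted up by a median of 0.20 over 57 genes (adjusted p = 3.44e-08, and adjusted p = 0.564 with an estimated correlation), with 0.107, 0.0992 and 0.280 on the single DDMB arrays, 0.157 without DDMB replicate 3 and 0.140 without VC_1 replicate 3. Crat (0.57) and Pdk4 (0.67) were among those that passed over all genes, and 13 rises and 1 fall passed adjusted over the list alone. Of 32 targets of CAR and PXR, the receptors behind much drug-metabolising enzyme induction, Cyp3a23-3a1 (0.53 ± 0.10, adjusted p = 0.0355) and the canalicular exporter gene Abcc2 (0.47) rose over all genes. Adjusted over the list alone 4 rose and 3 fell, and the list did not shift (adjusted p = 0.668). In the AhR list the only call of 15 genes was the fall of Aldh3a1 (1 rise and 2 falls adjusted over the list alone). Other camera shifts were a heat shock rise (median 0.14, adjusted p = 0.0210) and falls of the integrated stress response (-0.09, 0.00303) and of fatty acid synthesis (-0.12, 0.0210), with adjusted p = 0.930, 0.930 and 0.795 with an estimated correlation. Each was lost without DDMB replicate 2 (adjusted p = 0.0734, 0.217 and 0.0734), heat shock also without VC_1 replicate 3 (0.0577) and the stress response without VC_1 replicate 1 (0.140) or 2 (0.0506). The stress response median ran from -0.0200 without DDMB replicate 2 and -0.0247 without VC_1 replicate 1 to -0.150 without DDMB replicate 1 and -0.204 without VC_1 replicate 3, and that of fatty acid synthesis was -0.0761 without VC_1 replicate 1.

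In all, limma called 120 of 21574 genes with DDMB, 49 higher and 71 lower, and 18 by at least 2-fold. The arrays of the groups did not overlap for 14.2% of genes, where chance gives 10%. Fitting only the 6 arrays compared left 0 calls in limma (2136 genes lay at an unadjusted p under 0.05 in the fit of all arrays), so the calls rest on the spread pooled over all groups, and the count was 39 without DDMB replicate 3 and 40 without VC_1 replicate 2, against 53 without VC_1 replicate 1, 74 without DDMB replicate 2, 80 without VC_1 replicate 3 and 198 without DDMB replicate 1. With each array left out in turn, 32 of the 120 calls were kept every time, among them those of Aldh3a1, Cyp2c11, Sstr3, Nefm, Hspb1, Crat, Tat and Ass1. The call of Colq was lost without any one array (adjusted p = 0.0505 to 0.179), those of Cyp3a23-3a1, Pdk4, Cimip2a and Abcc2 without any except DDMB replicate 1 (0.0666 to 0.265), and that of Nefl without any except DDMB replicate 2 (0.0957 to 0.258). Pck1 and Hpd lost theirs without replicate 2 or 3 of either group (0.0649 to 0.139), Cpne9 and Spon2 without DDMB replicate 2 or 3 or VC_1 replicate 1 or 2 (0.0709 to 0.202), and Ogn without DDMB replicate 3 or any VC_1 replicate (0.0804 to 0.112). Without DDMB replicate 3 the calls of Cyp4b1 (0.0531), Abcg5 (0.0654), Pcp4l1 (0.0531), Gls2 (0.0531), Unc5d (0.121) and Car11 (0.0542) were lost. Those of Cyp4b1 (0.0524), Car11 and Procr (both 0.0612) were lost without VC_1 replicate 1, those of Procr (0.0647) and Unc5d (0.0543) without replicate 2, and those of Unc5d (0.0666) and Car11 (0.0607) without replicate 3.

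**Figure D1:**
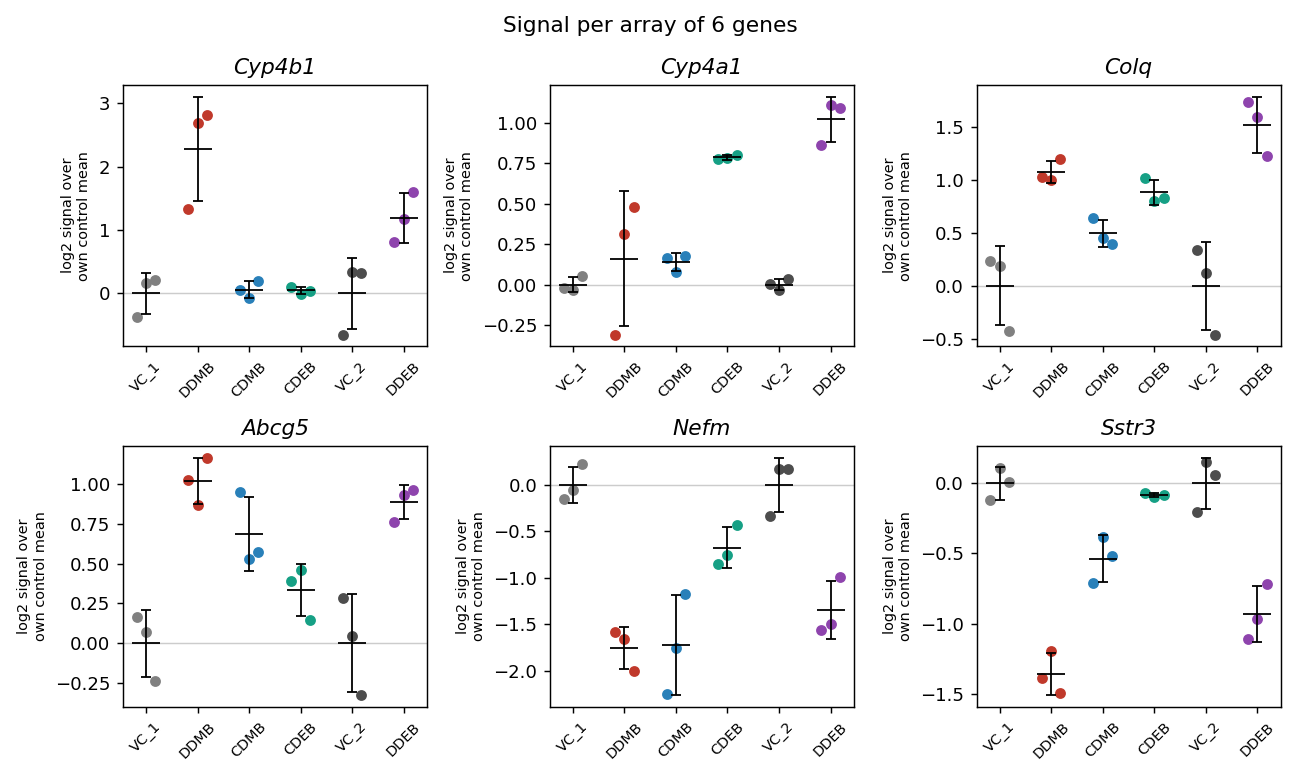
Log2 signal of 6 genes on each of the 18 arrays, relative to the mean of the group's own DMSO control. Points are arrays, the horizontal mark is the group mean and the bar 1 SD (n = 3). Cyp4b1 is highest with DDMB (1.33, 2.69 and 2.81 on single arrays). With DDEB it lies at 0.816, 1.17 and 1.59, above every VC_2 array (at most 0.330), but was not called. Cyp4a1 rises with DDEB (log2 1.02) and lies at 0.79 with CDEB.

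With DDEB, transcripts of several enzymes that oxidise fatty acids rose, while Hadha (0.21), Acadl (0.20) and Acsl1 (-0.01) of the same pathway were not called over all genes (Hadha and Acadl passed adjusted over the PPARalpha list alone). The fatty acid omega-hydroxylase genes Cyp4a1 and Cyp4a3 were higher than in VC_2 by 1.02 ± 0.14 and 0.88 ± 0.10 on the log2 scale (n = 3, adjusted p = 0.00609 and 0.00519). They were joined by the mitochondrial isomerase gene Eci1 (0.87 ± 0.16), the peroxisomal thiolase genes Acaa1b (0.75) and Acaa1a (0.70), the mitochondrial thiolase gene Acaa2 (0.70), Crat (0.73), Ucp2 (0.74), Ehhadh (0.65), Pdk4 (0.61) and the carnitine palmitoyltransferase gene Cpt2 (0.44). Of 57 measured PPARalpha targets 17 rose and none fell over all genes, and 38 rose and 1, Txnip (-0.67), fell adjusted over the list alone. The list shifted by a median of 0.40 (camera adjusted p = 2.76e-22). It missed the threshold at adjusted p = 0.0667 with an estimated correlation and passed with fry (adjusted p = 0.000219). Slide as a fixed block, which compares VC_2 with the 2 DDEB arrays on its slide, left the shift called (adjusted p = 4.11e-18). The spike-in ratio was 1.09%, 1.18% and 1.66% on DDEB replicates 1 to 3 and 1.73% to 1.83% on VC_2.

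Outside that list, the CAR and PXR target Cyp3a23-3a1 rose by 0.76 ± 0.10 (adjusted p = 0.0053), alone among 32 members over all genes and adjusted over the list alone. The stearoyl-CoA desaturase gene Scd (0.54), the kinase gene Plk3 (0.51), the glucose transporter gene Slc2a1 (0.41) and Gls2 (0.35) were each called in their lists. Adjusted over the list alone, their lists counted 1 rise for fatty acid synthesis, 1 for p53 targets, 3 for glycolysis and 2 for glucose synthesis. The glycolysis list rose by a median of 0.20 (adjusted p = 0.00303, and adjusted p = 0.965 with an estimated correlation), a call lost without VC_2 replicate 3 (median -0.004, adjusted p = 0.439) or DDEB replicate 1 (0.185). Colq (1.52 ± 0.20), Tmem117 (1.34, above background on 1 of 3 VC_2 arrays), Abcg5 (0.89) and Pcp4l1 (0.79) were among the 10 largest rises. The muscle calcium channel gene Cacna1s was at least 2.25-fold higher, Osbp2 at least 1.52-fold and Serpine2 at least 1.02-fold. The falls held Nefm (-1.35, above background on 1 of 3 DDEB arrays), Nxnl2 (-1.33), Myog (-1.05), Rprm (-1.05), Sstr3 (-0.93 ± 0.12), Cfap95 (-0.79) and Omd (-0.73). Lxn was at least 1.81-fold lower and Car11 at least 1.02-fold, while Dhrs7l1 was not well above background in either group.

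The DDEB response comprised 213 genes, 155 higher and 58 lower, with 28 changed at least 2-fold, and 16.5% of genes had arrays that did not overlap (10% by chance). These calls rest on the spread pooled over all groups. The mean variance was 0.161 in DDEB and 0.0809 in VC_2, against 0.0322 to 0.0858 in the other groups. The pooled spread was thus on average too narrow for this comparison, which favours calls. Fitted with VC_2 and DDEB alone, limma called 0 genes (3278 lay at an unadjusted p under 0.05 in the fit of all arrays). The deposited tables, fitted for DDEB on the same 6 arrays, also gave 0, so they are no separate check. In these fits Cyp4a1 had limma adjusted p = 0.323 and 0.374 at an unchanged log2 change of 1.02. Quantile normalization called 325 genes of which 47.7% were higher, against 72.8% as scaled here and 62.4% after normexp, and the count fell to between 51 and 69 without DDEB replicate 2 or any VC_2 replicate, 112 without DDEB replicate 1, and rose to 359 without DDEB replicate 3. Of the 213 calls, 30 were kept with each array left out in turn, among them those of Cyp4a1, Cyp4a3, Crat, Cyp3a23-3a1, Scd, Colq, Sstr3, Cfap95 and Omd. The calls of Pdk4 and Car11 were lost without any one array (adjusted p = 0.0615 to 0.163), those of Slc2a1, Osbp2, Lxn, Rprm and Dhrs7l1 without any except DDEB replicate 3 (0.0503 to 0.149), those of Plk3 and Serpine2 without any except DDEB replicate 1 (0.0705 to 0.156), and that of Ucp2 without any except VC_2 replicate 1 (0.0587 to 0.168). Acaa1b and Acaa2 lost theirs without DDEB replicate 2 or any VC_2 replicate (0.0588 to 0.0818), Myog without DDEB replicate 1 or any VC_2 replicate (0.0528 to 0.0859), Nefm and Cpt2 without DDEB replicate 1 or 2 or VC_2 replicate 2 or 3 (0.0550 to 0.0921), and Cacna1s without replicate 1 or 3 of either group (0.0547 to 0.115). The calls of Eci1, Gls2 and Abcg5 were lost without DDEB replicate 2, that of Eci1 also without VC_2 replicate 1 or 2, that of Gls2 without 1 or 3 and that of Abcg5 without 2 or 3 (0.0518 to 0.0896). Acaa1a, Ehhadh and Nxnl2 lost theirs without VC_2 replicate 1 or 2 (0.0511 to 0.0580), Tmem117 without replicate 1 (0.0508) and Pcp4l1 without replicate 3 (0.0600).

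**Figure D2:**
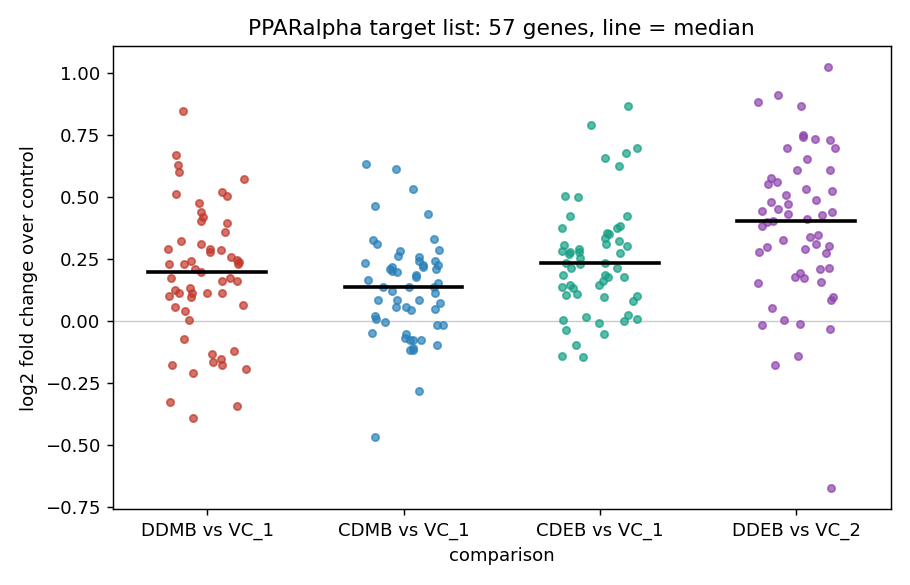
Log2 fold change over control of the 57 measured PPARalpha targets for each compound. Each point is a gene and the line is the median, which is 0.40 for DDEB, 0.24 for CDEB, 0.20 for DDMB and 0.14 for CDMB.

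CDMB changed few genes against VC_1, which lay on another slide. Hspb1 rose by 0.72 ± 0.11 (log2 ± SE, n = 3, adjusted p = 0.0325), and Nefm, above background on 1 of 3 CDMB arrays, had a log2 change of -1.73 ± 0.24 (adjusted p = 0.0211). The remaining 7 of the 9 called genes have no symbol here. Chaperones of the endoplasmic reticulum, which fold secreted proteins, rose as a list by a median of 0.24 over 27 genes (adjusted p = 6.55e-05, and adjusted p = 0.930 with an estimated correlation), with 0 members called in limma over all genes and 1 adjusted over the list alone, and a median of 0.130 without VC_1 replicate 3 (adjusted p = 0.0279). PPARalpha targets shifted by a median of 0.14 (adjusted p = 0.00102, and adjusted p = 0.930 with an estimated correlation), with 0 of 57 members called either over all genes or adjusted over the list alone. Glucose synthesis (0.27, adjusted p = 0.000243), glycolysis (0.25, 0.000243) and hepatocyte identity (0.21, 0.00201) rose, and cell cycle (-0.39, 0.000372) and p53 targets (-0.09, 0.00865) fell, with adjusted p = 0.930, 0.930, 0.965, 0.930 and 0.930 with an estimated correlation. Without VC_1 replicate 3 these calls were lost (medians 0.0883, 0.0995, 0.0685, -0.126 and -0.0654, adjusted p = 0.0535, 0.0621, 0.748, 0.311 and 0.104 in the same order), and without VC_1 replicate 1 the medians of glycolysis (0.381) and p53 targets (-0.154) were larger. VC_1 replicate 3 carried high cell cycle and low hepatocyte identity signal, with mean deviations of 0.54 and -0.39 from its group. The spike-in ratio also moved with the group, at 1.23% to 1.32% on the CDMB arrays and 1.98% to 2.04% on those of VC_1.

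None of the 9 calls was kept throughout when each array was left out in turn. The call of Hspb1 was lost without any one array (adjusted p = 0.0514 to 0.209) and that of Nefm without any except CDMB replicate 3 (0.0622 to 0.108). The CDMB count of 9 genes had 7 higher and 2 lower, with 2863 genes at an unadjusted p under 0.05 in limma, and 25.5% of genes had arrays that did not overlap (10% by chance). With slide as a random block, with only the 6 arrays compared, without CDMB replicate 2 or without any VC_1 replicate the count was 0, it was 1 without CDMB replicate 3, and compound and slide cannot be told apart here.

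CDEB was also set against VC_1 across slides. Cyp4a3 rose by 0.62 ± 0.10 (log2 ± SE, n = 3, adjusted p = 0.0343) and Scd by 0.56 ± 0.07 (adjusted p = 0.00817), while Cyp4a1 had a log2 change of 0.79 ± 0.14 and missed the threshold (adjusted p = 0.0528). The chemokine gene Cxcl12 (0.61), the talin gene Tln2 (0.47), Galnt2 (0.38) and the peptidase gene Dpp9 (0.37) were the other named rises. Ppp1r37 (-0.71 ± 0.08), Sat2 (-0.45), the folliculin gene Flcn (-0.41) and Gga2 (-0.38) fell. PPARalpha targets shifted by a median of 0.24 (adjusted p = 7.93e-12, and adjusted p = 0.302 with an estimated correlation), with 1 rise over all genes and 14 adjusted over the list alone, and fry gave adjusted p = 0.0112. Glycolysis rose (median 0.30, adjusted p = 2.33e-07), and so did hepatocyte identity (adjusted p = 0.000243) and glucose synthesis (0.20, 0.00221), while cell cycle fell (-0.44, 0.000236), with adjusted p = 0.930, 0.965, 0.930 and 0.930 with an estimated correlation. Without VC_1 replicate 3 glycolysis stayed called (0.000178), whereas hepatocyte identity (median 0.0652, adjusted p = 0.402), glucose synthesis (0.0728, 0.222) and cell cycle (-0.194, 0.195) did not. The spike-in ratio was 1.21% to 1.28% on the CDEB arrays, below the 1.98% to 2.04% of VC_1.

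For CDEB, 29 genes were called, 15 higher and 14 lower, none by 2-fold, with 2870 genes at an unadjusted p under 0.05 in limma and 29.3% with arrays that did not overlap (10% by chance). With slide as a random block or only the 6 arrays compared the count was 0, leaving out CDEB replicates 1, 2 and 3 gave 8, 0 and 5, leaving out VC_1 replicates 1, 2 and 3 gave 9, 3 and 5, and compound and slide cannot be told apart here either. Leaving out each array in turn, none of the 29 calls was kept throughout. The calls of Cyp4a3, Cxcl12, Tln2, Galnt2, Dpp9, Flcn and Gga2 were lost without any one array (adjusted p = 0.0635 to 0.206), and those of Scd, Ppp1r37 and Sat2 without CDEB replicate 2 (0.068, 0.0552 and 0.0552).

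Several genes fixed in advance as readouts of other responses passed for none of the compounds. Cyp1a1, the classical AhR target, had log2 changes from 0.67 to 1.09 with a standard error of 0.64. The NRF2 targets Nqo1 (-0.12 to 0.08), Hmox1 and Gclc, the p53 targets Cdkn1a and Mdm2, the stress genes Atf3 and Ddit3, the bile acid synthesis gene Cyp7a1, and Alb, which encodes albumin, were not called. For Cyp7a1 the values ran from -0.84 to 1.55 with a standard error of 0.83. No list of another cell type shifted (adjusted p at least 0.803). The endothelial, lymphocyte and erythrocyte lists had under 5 measured genes and the neutrophil list had none.

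**Figure D3:**
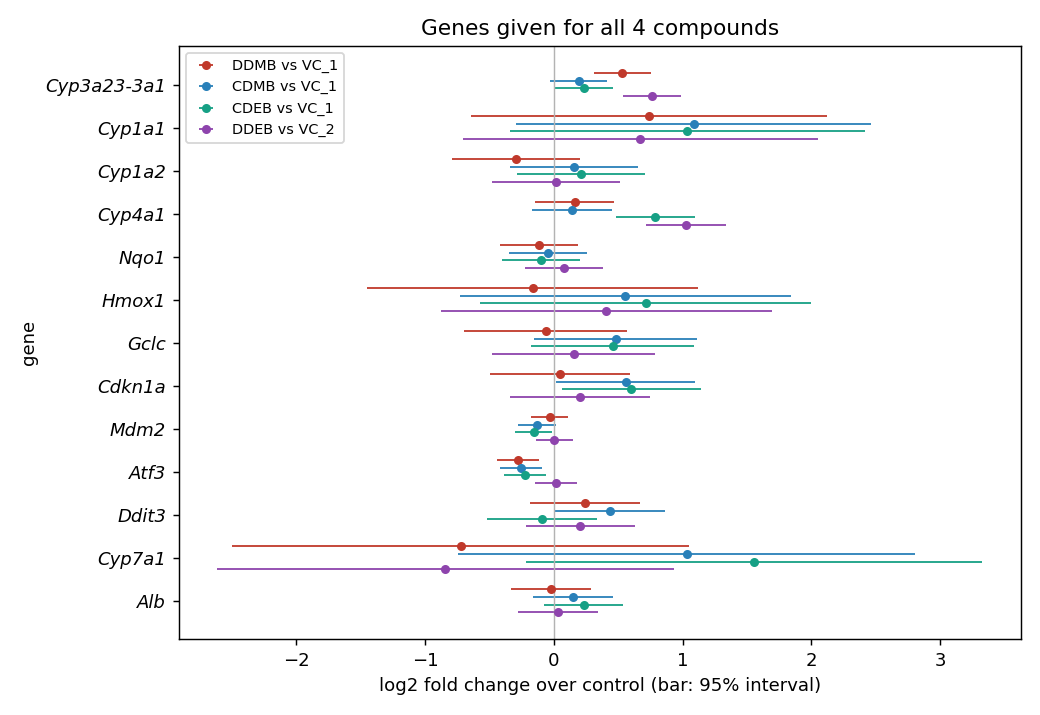
Log2 fold change over control of 13 genes fixed in advance, for the 4 compounds. Points are limma estimates and bars their 95% intervals, which are not adjusted for the number of genes. The calls among them are Cyp3a23-3a1 with DDMB and DDEB, and Cyp4a1 (1.02) with DDEB.

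The compounds were then compared with each other at the same concentration and time. DDMB gave higher Cyp4b1 than CDMB (log2 difference 2.22, 95% interval 1.47 to 2.98, adjusted p = 0.0125) and than CDEB (2.23, 1.48 to 2.99, adjusted p = 0.00663), and higher Pck1 (1.20, 0.76 to 1.63, and 0.80, 0.37 to 1.24). With DDEB, Cyp4b1 lay at 0.816 to 1.59 over the VC_2 mean on single arrays, and its difference from DDMB was not called. The CAR-responsive P450 gene Cyp2b2 was lower with DDMB than with CDMB (-1.49, -2.11 to -0.87) or CDEB (-1.54, -2.16 to -0.92). Against CDMB, the latent TGF-beta binding protein gene Ltbp1 (1.15) and Atp6v0d2 (0.72) were higher and Prickle2 at least 1.36-fold higher, and the complement protease gene Masp1 (-0.91), Col5a3 (-0.88), Cxcl12 (-0.88) and Sstr3 (-0.82) were lower. Against CDEB, Cyp4a1 was lower with DDMB (-0.63, -0.94 to -0.32, adjusted p = 0.0341), while Dpm1 (0.88, above background on 2 of 3 CDEB arrays) and Gas2l3 (0.81) were higher and Ugt2b7 at least 1.38-fold higher. Slurp2 (-2.03, above background on 2 of 3 DDMB arrays), C7h12orf75 (-1.67, on 1 of 3), Cd209f (-1.65) and Tmbim7 (-1.54) were lower. The counts were 152 genes against CDMB (65 higher, 87 lower) and 695 against CDEB (331 higher, 364 lower). Leaving out 1 replicate gave 21 to 532 genes against CDMB (532 without DDMB replicate 1) and 106 to 934 against CDEB, and 18 of the 152 and 82 of the 695 calls were kept every time, among them Cxcl12 against CDMB and Cyp4b1 and Cd209f against CDEB. Against CDMB, the calls of Pck1, Cyp2b2, Ltbp1, Masp1 and Prickle2 were lost without any one array except DDMB replicate 1 (adjusted p = 0.0516 to 0.157), those of Cyp4b1 and Col5a3 without replicate 2 or 3 of either group (0.0600 to 0.0737), that of Atp6v0d2 without DDMB replicate 2 or 3 or CDMB replicate 2 (0.0531 to 0.0594), and that of Sstr3 without DDMB replicate 3 or CDMB replicate 2 or 3 (0.0549 to 0.0594). Against CDEB, the calls of Pck1, Gas2l3, Slurp2 and Tmbim7 were lost without any one array except DDMB replicate 1 (0.0556 to 0.181), those of Dpm1 and Ugt2b7 without any except CDEB replicate 1 (0.0638 to 0.171), and those of Cyp4a1, Cyp2b2 and C7h12orf75 without DDMB replicate 2 or any CDEB replicate (0.0533 to 0.122). These compounds lay on different slides, and with slide as a random block both counts were 0 in limma (3553 and 4361 genes at an unadjusted p under 0.05 without the block). That block widens comparisons across slides by construction, so these counts of 0 decide nothing about the slide.

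CDMB and CDEB shared a slide, and limma called 0 genes between them (smallest adjusted p 0.102). Of 21574 genes 1018 lay at an unadjusted p under 0.05, which is below the share of 0.05 that chance gives. However, 19.5% of genes had arrays that did not overlap, which is above the chance share given for the controls. The mean variance was 0.0471 in CDMB and 0.0322 in CDEB, against 0.0800 to 0.161 in the other groups. The pooled spread was thus on average too wide for this pair, which works against calls. The low share of small p-values therefore does not show that a difference is absent. Cyp4a1 was lower with CDMB by an estimate of -0.65 (95% interval -0.96 to -0.34, adjusted p = 0.370) and Cyp3a23-3a1 differed by -0.04 (-0.26 to 0.18). Single arrays of Cyp4a1 lay at 0.0753 to 0.180 with CDMB and 0.776 to 0.805 with CDEB (log2 over the VC_1 mean). Its interval rests on the spread pooled over all groups, which includes DDMB arrays at -0.310 to 0.481. Fitting only the 6 arrays of CDMB and CDEB also gave 0 genes. Between DDEB and DDMB, each over its own control, limma also called 0 genes (1249 at an unadjusted p under 0.05, little above the chance share), and 2 with the replicate number as a block. The difference was 0.86 for Cyp4a1 (0.43 to 1.30, adjusted p = 0.453) and 0.23 for Cyp3a23-3a1 (-0.08 to 0.54). DDEB and CDMB gave 0 called genes in limma as well (1251 at an unadjusted p under 0.05, and 2 called with that block), with 0.88 for Cyp4a1 (0.45 to 1.32, adjusted p = 0.670). DDEB and CDEB differed in 2 genes (1432 at an unadjusted p under 0.05), Sat2 (0.52, 0.36 to 0.67, adjusted p = 0.0474, lost without any one array except DDEB replicate 3) and a transcript without a symbol (1.27, adjusted p = 0.00794), and with the replicate number as a block neither call was kept (Sat2 0.52, adjusted p = 0.128). Cyp4a1 differed by 0.23 (-0.20 to 0.67). These intervals rest on the spread pooled over all groups and leave room for differences, so the counts of 0 do not show that the compounds act alike. Between compounds the mean over arrays of the PPARalpha list median was higher with DDEB than with DDMB by 0.235, CDMB by 0.259 and CDEB by 0.149, and lower with CDMB than with CDEB by 0.110. In a two-sided exact permutation test chosen after these values were seen, each had p = 0.1, the smallest that 3 arrays against 3 can give (adjusted p = 0.15 over 6 comparisons). It takes the control means as fixed. Arrays of DDEB and of another compound carry the errors of different controls, so there the test is not exact for a difference between compounds. It also takes no account of the slides. In the same permutation test DDMB differed from CDMB by 0.0246 (exact p = 0.8) and from CDEB by -0.0851 (exact p = 0.4).

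The DMSO controls on the chip lots differed far more than any compound from its control. VC_2 had 4678 genes changed against VC_1, 2731 higher and 1947 lower, with 1019 by at least 2-fold. A fit of the 6 control arrays alone gave 3571, and 10778 with the replicate number as a block. The muscle creatine kinase gene Ckm was higher in VC_2 by 4.69 ± 0.33 (log2 ± SE, n = 3) and Ccl12 by 3.91 ± 0.68, each above background on 2 of 3 VC_1 arrays, Nkx2-3 at least 9.68-fold, the complement receptor gene C3ar1 at least 5.02-fold and Cd80 at least 4.25-fold. Wdr62 (-1.28 ± 0.13) and Rassf2 (-1.23 ± 0.20) were lower in VC_2, and Tox2, Serpine2 and Gtf2a1l were not well above background there. Of the genes fixed in advance Mdm2 was called (0.20, adjusted p = 0.0456). Among the 4678 calls, 2558 were kept with each array left out in turn. That of Gtf2a1l was lost without any one array (0.0529 to 0.170), that of Mdm2 without VC_2 replicate 2 or 3 or VC_1 replicate 1 or 2 (0.0750 to 0.167), and that of Serpine2 without VC_2 replicate 2 or VC_1 replicate 1 (0.0702 to 0.0813). Quantile normalization gave 46.6% higher calls, against 58.4% as scaled here.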

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

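The splits of arrays given here were planned and counted for every comparison, and no test in this part was chosen after its result was seen. Among the 6 tested differences between compounds, 3 held called genes. DDMB and CDMB differed in 152 genes, led by Cyp4b1, Pck1 and Cyp2b2, and DDMB and CDEB in 695 genes, which include Cyp4a1 and Cyp2b2. DDEB and CDEB differed in 2 genes, Sat2 and a transcript without a symbol, each tested as the difference of the effects over the compounds' own controls. Leaving out each array in turn, 18 of the 152, 82 of the 695 and 1 of the 2 calls were kept every time, and those of Cyp4b1, Pck1 and Cyp2b2 against CDMB, Cyp4a1 and Cyp2b2 against CDEB and Sat2 were not. Each is given because a test of the difference itself called genes, which does not separate the compounds from their slides. DDMB lay on another slide than CDMB and CDEB, and so did DDEB from CDEB. With slide as a random block the counts in limma were 0, 0 and 0 (3553, 4361 and 1432 genes lay at an unadjusted p under 0.05 without the block). The random block widens comparisons across slides by a correlation that rests on DDEB replicate 3, so these counts of 0 do not test the slide. With the replicate number as a block neither call of DDEB vs CDEB was kept. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of these 10, 1 split, the real one, gave as many genes in DDMB vs CDMB (152, the highest other 1), DDMB vs CDEB (695, the highest other 0) and DDEB vs CDEB (2, the highest other 0). In CDMB vs CDEB, DDEB vs DDMB and DDEB vs CDMB the real split gave 0 genes, and so did every other one of the 10 splits.

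Against the controls, 1 of 10 splits gave as many genes in each comparison, the real one, with 120 for DDMB (highest other 0), 213 for DDEB (4), 9 for CDMB (0), 29 for CDEB (0) and 4678 for VC_2 against VC_1 (1). The counts of called gene lists stood apart less. For DDMB the real split called 8 lists, 3 of 10 splits called as many, and the highest other called 10. For CDMB the real split called 7, reached by 3 of 10, with 11 as the highest other. For DDEB (2 lists) and CDEB (5 lists) 10 of 10 splits called as many, with 10 and 9 as the highest others. Some splits that mix compound and control thus call as many lists at the preset correlation, so these counts of lists cannot be credited to the compounds. The cause was not tested.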

How the results depend on the processing

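The alternative that leaves out 4 arrays sharing a deviation (VC_1 replicate 3, VC_2 replicate 3, DDMB replicate 2 and DDEB replicate 3) was the only one chosen after seeing the data. Picking them by that deviation shrinks the spread by construction. Over the alternatives, 11251 values of named genes stayed, 629 lost and 182 gained a call, 175 moved and 12 reversed. For genes called in neither fit, small shifts count as stayed whatever their direction, and larger ones as moved. The 12 reversals are changes of direction with a call in the alternative. Of the values of gene lists, 589 stayed, 95 lost the call, 4 moved and 2 reversed. The signal over background limits genes near the floor, whose folds are bounds. Except where a construction is named, the cause was not tested.

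With only the 6 arrays compared, counts were 0 for DDMB, DDEB, CDMB, CDEB and DDMB vs CDMB and 13 for DDMB vs CDEB. This fit has fewer arrays to estimate the spread, and the mean variance was 0.161 in DDEB against 0.0322 in CDEB. The spread pooled over all groups was thus on average too narrow for DDEB against VC_2 and too wide for CDEB against VC_1. The counts of called genes therefore do not rank the compounds. Separate fits of the control sets gave 0 for DDEB, 1 for CDMB, 8 for CDEB and 1137 for DDMB vs CDEB. The deposited values, fitted in the same sets, gave 0, 1, 8 and 1240, so they do not test the deposited scaling by itself. Without the filter on dim probes, counts were 49 for DDMB, 0 for CDMB, 6 for CDEB, 42 for DDMB vs CDMB, 144 for DDMB vs CDEB, 11 for DDEB vs DDMB, 7 for DDEB vs CDMB, 8 for DDEB vs CDEB and 13125 for VC_2 vs VC_1. Probes detected on all arrays gave 235 for DDMB vs CDMB. Normexp gave 20 for CDMB, 17 for CDEB and 0 for DDEB vs CDEB, and quantile normalization 325 for DDEB and 1 for DDEB vs DDMB. Higher calls made up 47.7% of the DDEB count after quantile normalization and 62.4% after normexp (72.8% as scaled here). They made up 29.9% for DDMB after quantile normalization (40.8%), 46.6% for VC_2 vs VC_1 (58.4%), 64.7% for CDEB after normexp (51.7%), 63.6% for CDMB with the percentile over detected probes (77.8%) and 66.7% of the 3 genes of DDEB vs CDEB after quantile normalization (100%).

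Slide as a random block gave 189 for DDMB, 0 for CDMB, CDEB, DDMB vs CDMB, DDMB vs CDEB and DDEB vs CDEB, and 580 for VC_2 vs VC_1. Its correlation rests on DDEB replicate 3, 1 of the arrays that share a deviation, so the counts across slides do not test the slide. As a fixed block, which takes DDEB replicate 3 out because it is alone on its slide, slide gave 245 for DDMB and 359 for DDEB. The replicate block gave 10778 for VC_2 vs VC_1, the only groups whose numbers pair the arrays. That fit held the 6 control arrays alone, which gave 3571 without the block. Elsewhere samples share only a number, and the block gave 9 for CDEB, 246 for DDMB vs CDMB, 1187 for DDMB vs CDEB, 2 each for DDEB vs DDMB and DDEB vs CDMB and 1 for DDEB vs CDEB, which is neither of its 2 calls without the block, with other counts within 1.5 times. Every array correlated best with its own number in VC_1 with VC_2 (6 of 6), 4 of 6 did in DDEB with VC_2 (lowest pair 0.0962), 3 of 6 in DDMB with VC_1 (-0.421) and in CDMB with VC_1 (0.014), and 4 of 6 in CDEB with VC_1 (-0.00234).

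The other control gave 6293 for DDMB, 5540 for DDEB, 6613 for CDMB and 6266 for CDEB, and both controls pooled 419, 563, 218 and 404. These hold the difference of the chip lots, as do the reversals with the other control, namely Nkg7 for DDMB (-1.25), CDMB (-0.98) and CDEB (-1.18), Hba-a1 for DDMB (-1.11), CDMB (-1.04), CDEB (-1.01) and DDEB (0.81), Cdh5 for CDMB (-0.51), and Myog (0.93), Slc39a14 (0.24), Aif1 (1.36) and Cd3d (0.53) for DDEB. The trend with robust prior gave 266 for DDMB vs CDMB and 0 for DDEB vs CDEB. At least 2-fold changes numbered 18 for DDMB, 28 for DDEB, 2 for CDMB, 0 for CDEB, 10 for DDMB vs CDMB, 45 for DDMB vs CDEB, 1 for DDEB vs CDEB and 1019 for VC_2 vs VC_1. At an adjusted p below 0.01 the numbers were 44, 28, 0, 5, 23, 104, 1 and 2456. Without the 4 arrays that share a deviation they were 342 for DDMB, 334 for DDEB, 60 for CDMB, 78 for CDEB, 19 for CDMB vs CDEB, 595 for DDMB vs CDMB, 2009 for DDMB vs CDEB and 6 for DDEB vs CDEB.

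Leaving out 1 replicate at a time gave 39 to 198 for DDMB, 51 to 359 for DDEB, 0 to 6 for CDMB, 0 to 9 for CDEB, 0 to 1 for CDMB vs CDEB, 21 to 532 for DDMB vs CDMB, 106 to 934 for DDMB vs CDEB, 0 to 1 for DDEB vs DDMB, 0 to 3 for DDEB vs CDMB, 1 to 6 for DDEB vs CDEB and 3256 to 4144 for VC_2 vs VC_1. Of the 76 list tests 22 were called. An estimated correlation left 0, fry 3, the other control 8 and leaving out a replicate 12 to 25, with 12 without VC_1 replicate 3. On leaving out a replicate, the adjusted p for DDMB ranged from 0.00017 to 0.748 for the cell cycle list, which turned upward without VC_1 replicate 3 (0.748), and from 2.94e-05 to 0.967 for glycolysis, which turned downward in camera without DDMB replicate 1 (0.967) and lost its call, with a median of -0.019, without VC_1 replicate 3 (0.896).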

Other observations

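Tests chosen after a result had been seen are the splits of the PPARalpha list, its permutation test between compounds, the medians without the 4 arrays that share a deviation, the cell cycle list without VC_1 replicate 3, and the correlations of control arrays without their leading component. DDMB and DDEB, which have different control arrays, called genes in common. Of these, 15 rose in both (0.352 expected of independent lists) and 23 fell in both (0.191 expected), with 0 in opposite directions. Among the shared rises were Abcg5, Colq, Crat, Abcd3, which encodes a transporter of the peroxisomal membrane, Cyp3a23-3a1, Gls2, Pdk4 and the proprotein convertase gene Pcsk5. The shared falls included Sstr3, Nefm, the Indian hedgehog gene Ihh (log2 -0.87 with DDMB), the plasma selenium carrier gene Selenop (-0.66), Slc9a9 (-0.74) and Pla1a. Crat and Sstr3 kept both calls with each array left out in turn. Abcd3 lost its call without any one array with DDMB (adjusted p = 0.0537 to 0.265). With DDEB, Ihh lost its call without any one array (0.0647 to 0.144), Selenop without DDEB replicate 1 or any VC_2 replicate (0.0639 to 0.0791), Pla1a without DDEB replicate 1 or 2 or VC_2 replicate 2 or 3 (0.0511 to 0.0624), Abcd3 and Pcsk5 without DDEB replicate 2 or VC_2 replicate 2 or 3 (0.0588 to 0.0755), and Slc9a9 without VC_2 replicate 1 or 2 (0.0640 and 0.0643). Other pairs with DDEB overlapped too. DDEB shared 9 rises (0.108 expected) and 2 falls (0.0376) with CDEB, with 1 gene in opposite directions, and 5 rises (0.0503) and 2 falls (0.00538) with CDMB. These expected counts take the controls as independent, whereas VC_1 and VC_2 deviate together by number, so they may be too low. DDMB shared 1 rise and 2 falls with CDMB, and 0 rises and 0 falls with CDEB, with 1 gene in opposite directions. These compounds have the same control. Independent lists would share 0.0341 rises and 0.0461 falls between DDMB and CDEB. With so few calls, the counts of 0 do not set CDEB apart from DDMB. Over all genes the fold changes of DDMB and DDEB correlated at r = 0.283. Their covariance of 0.0197 is hardly above the 0.0188 between the mean deviations of VC_1 and VC_2 arrays of the same number, and those of DDEB with CDMB (0.0155) and CDEB (0.0127) lie below it, so controls that deviate together may account for the correlation over all genes.

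CDMB and CDEB, which share both slide and control, had fold changes that correlated at r = 0.756 across genes. Shared controls alone gave 0.499 in a simulation with the same spread in every group. Mean variances were 0.0471 for CDMB and 0.0322 for CDEB against 0.0800 for VC_1, so 0.499 is too low as a reference for this r. The covariance of CDMB and CDEB, which for independent groups depends on VC_1 alone, was 0.0611, against 0.0269 simulated. They shared 3 rises, for which controls in common leave no expected count here, and the slide is common to both. For DDMB with CDMB the covariance was 0.0246 (0.0267 simulated), and with CDEB 0.0186 (0.0269). Lists that shifted with no compound were those of CAR and PXR (lowest adjusted p 0.077), NRF2 (0.0842), metallothioneins and zinc transport (0.0871), cytoskeleton and matrix (0.264), AhR (0.277), apoptosis (0.281), cholesterol synthesis (0.281) and bile acids (0.681). For DDMB, glycolysis rose (median 0.17, adjusted p = 0.0196, and adjusted p = 0.965 with an estimated correlation), and cell cycle (-0.16, 0.0361, and adjusted p = 0.965 with an estimated correlation) and acute phase genes (-0.19, 0.0376, and adjusted p = 0.930 with an estimated correlation) fell. Glycolysis had a median of 0.285 without DDMB replicate 2. It lost its call without VC_1 replicate 3 (median -0.019, adjusted p = 0.896) or DDMB replicate 1 (-0.007, 0.967), cell cycle without VC_1 replicate 3 (median 0.016, adjusted p = 0.748) or DDMB replicate 1 (0.585) or 3 (0.121), and acute phase genes without DDMB replicate 2 (0.287) or 3 (0.204) or VC_1 replicate 1 (0.152) or 2 (0.0830). The cell cycle median was -0.0723 without DDMB replicate 1. It was -0.359 without VC_1 replicate 1, -0.299 without DDMB replicate 2 and -0.260 without VC_1 replicate 2. The acute phase median was -0.0334 without DDMB replicate 2, -0.0641 without VC_1 replicate 1 and -0.111 without VC_1 replicate 2. Without VC_1 replicate 3 the hepatocyte identity list was lower with DDMB (-0.20, camera adjusted p = 1.85e-06), which with all arrays was not called (adjusted p = 0.0895). List tests that leave out an array used only the preset correlation, so this value has no counterpart with an estimated correlation.

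The PPARalpha shift with DDEB is the pattern most open to follow-up. Among medians of 10000 random lists matched on mean signal it stood at percentile 100 (highest random median 0.132), which argues against probe brightness. The lists of DDMB (0.198, highest random median 0.120), CDEB (0.235, 0.114) and CDMB (0.138, 0.104) also stood at percentile 100, so this does not set DDEB apart. For DDEB, without the arrays that share a deviation the median was still 0.330 of 0.405, which argues against those arrays as the cause. Of 10 splits 1, the real one, gave as large a median (highest other 0.201), too few splits for a share under 0.05. The spike-in ratio of DDEB replicates 1 and 2 (1.09% and 1.18%) lay below that of VC_2 (1.73% to 1.83%), but DDEB replicate 3, with 1.66%, had a list median of 0.389 over VC_2, and since it is 1 array on a slide of its own, a labelling difference cannot be told apart from the compound. A response of PPARalpha targets to DDEB remains a hypothesis and may be the biological explanation, to be weighed with the adjusted p of 0.0667 for the list with an estimated correlation. When VC_2 and DDEB are fitted alone the fold of Cyp4a1 is unchanged (log2 1.02) and its call is lost (adjusted p = 0.323), in a fit with fewer arrays to estimate the spread.

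CDMB and CDEB were hybridised on another slide than VC_1, so their calls may come from the slide. The planned test set the higher of their counts, 29, against the 4678 genes between the DMSO groups. These differ in chip lot as well as slide, so a count below 4678 decides nothing about a slide effect within one lot. The spike-in ratio differs with the slide too (1.21% to 1.32% on the arrays of both compounds, 1.98% to 2.04% on VC_1). No VC_1 array shares a slide with these compounds, so slide, labelling and compound cannot be told apart, and a response to the compounds remains open.

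The lower cell cycle list with CDMB and CDEB may reflect VC_1 replicate 3 more than the compounds. Without that array the median was -0.194 for CDEB, from -0.439, and -0.13 for CDMB, from -0.39. The array shares its deviation with VC_2 replicate 3, DDMB replicate 2 and DDEB replicate 3, where the cell cycle list lay 0.45 to 0.73 above the group mean and hepatocyte identity and glycolysis lay below it. The component that separates these arrays held 45.5% of the variation within groups. A smaller effect of the compounds on the list remains open.

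A hypothesis from the control arrays is that VC_1 and VC_2 are the same cultures or RNA hybridised on both chip lots. Same-numbered arrays deviated together, and after the leading component was taken out the lowest same-number correlation was 0.143 and the others 0.279 and 0.289, whereas different numbers gave -0.24 to -0.04. Deviations within a group sum to 0, which forces part of that contrast, and there are only 6 ways to pair 3 arrays with 3. No label states such a reuse, and if it holds, the 4678 genes between the controls would measure chip lots more than cultures.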
